A study of Mus musculus with 6 samples.

How the data were processed

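Gene expression was measured by RNA sequencing in 6 libraries of mouse adipose-derived stem cells (ADSC), which are stromal cells grown from fat tissue. Per the labels, 3 libraries came from mock cultures and 3 from cultures transduced with the integrins VLA-4 (subunits Itga4 and Itgb1) and LFA-1 (subunits Itgal and Itgb2). The labels differ on what mock means: the treatment protocol names an empty vector, while the design text calls the comparison cells unmodified and the sample label gives the genotype as wild type. Groups and replicate numbers were taken from the sample titles. No label says whether the 3 libraries of a group came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical.

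The submitters' processing notes name fastp, HISAT2 (version 2.0.5), StringTie (version 1.3.3b), featureCounts (version 1.5.0-p3) and the mouse build mm39, without the role or order of each. The annotation release, the strand setting and any filter are not given in the sources used here. The authors deposited raw counts per gene and library, which are whole numbers with a different total in each library. They also deposited FPKM values, and comparing these with the counts showed a per-library scale of 0.964 to 0.966 of the total count in the mock libraries and 1.04 to 1.06 in the others, so the FPKM values carry a scaling factor besides depth. The deposited group means are a signal made from counts divided by a size factor per library. The authors' deposited log2 fold changes and p-values come from a comparison whose tool is not given in the sources used here, but a DESeq2 refit of the counts differed from them by at most 2.6e-05 in log2 fold change and 9.3e-06 in p. Their adjusted p is exactly 1 for 9070 genes, and 2740 genes with 1 count in all were not compared.

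The table held 56748 genes, of which 28731 had at least 1 count. Library totals ran from 15723888 to 18381083 counts. A gene with no counts in a library was therefore below 0.163 to 0.191 CPM (counts scaled to a common library size), the level of 3 counts in that library. Intervals and floors cover counting error only, at 95% confidence. The counts were tested with the quasi-likelihood test of edgeR (version 4.0.16, in R version 4.3.3) after TMM scaling and the filterByExpr filter with a minimum count of 10, which left 14502 genes. The model held the group and no replicate block. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05 and no fold minimum. Log2 fold changes are the libraries labelled overexpressing minus the libraries labelled mock, and each standard error (SE) is the log2 fold change divided by the square root of its F statistic. Levels are CPM on TMM-scaled library sizes, as mean ± SD over 3 libraries.

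The procedure was tested on simulated counts drawn for this comparison over 14281 genes. It recovered 93% of the genes changed by 2-fold and 75% of those changed by 1.5-fold, and 12 of its 180 calls (6.67%) were false. The changed genes, 100 of each size, had a mean of at least 1 CPM. They went up and down equally, with no scaling difference between libraries besides depth. The recovery therefore does not cover genes of lower level, and neither rate covers data in which 45.3% of genes change. No pair of libraries in a group agreed within sampling noise: chi-square per degree of freedom, over genes with at least 20 counts, was 3.55 to 7.47, so each library counted as 1 replicate.

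The tests, the alternatives, the gene lists and the rule for named genes were set before the data were examined, except where stated. The rule took the 4 transduced subunits, the 12 higher and 12 lower protein-coding genes with the largest fold change, the 5 higher and 5 lower with the smallest p, and up to 4 members of each list with the smallest p. Genes of the size and p rules needed an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between the groups, and predicted genes named Gm or Rik were left out. There were 28 lists, of which 26 had at least 5 tested members and a set test. They covered integrin subunits, adhesion molecules, integrin signalling, inflammatory genes, immunomodulatory factors, interferon-stimulated genes, MHC class I presentation, matrix, proteases and migration, mesenchymal, adipogenic, osteogenic and chondrogenic genes, and smooth muscle. They also covered macrophage, endothelial, lymphocyte and mesothelial markers, the cell cycle, p53 targets, cholesterol synthesis and efflux, hypoxia and glycolysis, the unfolded protein response, antioxidant genes, mitochondrially encoded genes, immediate early genes and ribosomal proteins. Of 782 list entries, 1 symbol (Rigi) had no match in the table. Set tests were camera in limma (version 3.58.1) with a preset correlation of 0.01, adjusted over the lists, then camera with an estimated correlation, fry, and 10000 random lists matched on expression.

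Alternatives were RLE factors, library size only, DESeq2 (version 1.42.0), limma-voom, no filter, a filter of 1 CPM in 3 libraries, robust dispersion, a replicate block, each library left out in turn, a 2-fold minimum, an adjusted p of 0.01 and protein-coding genes only. A smooth correction for gene length and transcript GC content (loess span 0.5) was added after seeing the data, as were 5 further lists: mRNAs with a 5-prime terminal oligopyrimidine tract (TOP), heat shock proteins, lysosome and autophagy genes, Schwann cell markers and melanocyte markers. Some Schwann cell markers count in their list but are not reported singly here. Gene positions and lengths are those of the deposited table. GC content came from transcripts of another mouse build (GRCm38), matched by gene identifier for 99% of the genes, and no coordinate was taken from it.

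The strand setting limits what the counts can tell: reads of a gene and of an overlapping or antisense gene could not be told apart. Genes with near-identical copies can share or lose reads, which makes Tgtp2, Iigp1, Ifi206, H2-T22, H2-T23, Hspa1b, Lce1l and the ribosomal protein genes uncertain. The vector sequence was not used here, so transgene reads that differ from the mouse genes were not counted.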

Results

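The series asked how carrying VLA-4 and LFA-1 alters ADSC. These integrins are the leukocyte receptors for VCAM-1 and ICAM-1, the adhesion molecules of inflamed vessel walls. The data were gene counts from 3 libraries labelled mock and 3 labelled overexpressing, with totals of 16904703 to 18381083 counts in the first group and 15723888 to 18185832 in the second. Between 21198 and 22438 genes had a count in a library. The first principal component held 70.9% of the variance and separated the groups, and the second held 7.72%.

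The overexpressed subunits were examined first, because they check the labels. None of the 4 was higher in the libraries labelled overexpressing. Itga4 (ENSMUSG00000027009, chromosome 2, 79085770 to 79163467, mm39) had 6.51 ± 1.48 CPM in the libraries labelled mock and 2.51 ± 0.28 CPM in those labelled overexpressing (SD, n = 3), a log2 fold change of -1.38 (SE 0.21, edgeR adjusted p = 1.28e-05). Itgb1 (ENSMUSG00000025809, chromosome 8, 129412135 to 129459681) fell from 2784 ± 44.6 to 2228 ± 123 CPM, a log2 fold change of -0.32 (SE 0.058, edgeR adjusted p = 9.16e-05). Itgal (ENSMUSG00000030830, chromosome 7, 126895432 to 126934310) had 7 counts over each group of 3 libraries, a ratio of 0.966 with a 95% counting interval of 0.289 to 3.23. Itgb2 (ENSMUSG00000000290, chromosome 10, 77366086 to 77401542) had 38 counts over the libraries labelled mock and 15 over those labelled overexpressing, a ratio of 0.381 (0.195 to 0.709). No library exceeded 0.247 CPM for Itgal or 1.02 CPM for Itgb2, and neither gene passed the filter. Without the filter their edgeR adjusted p-values were 0.994 and 0.109. The call of Itgb2 depended on single libraries: it passed the filter and was lower without mock replicate 3 (adjusted p = 0.0361) and without overexpressing replicate 3 (adjusted p = 0.0265), and it passed the filter without a call when overexpressing replicate 1 or 2 was left out (adjusted p = 0.173 and 0.198). The positions are whole gene spans, and all 4 genes are protein-coding. Because these genes go against the label, every direction given here is between libraries as labelled.

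**Figure D1:**
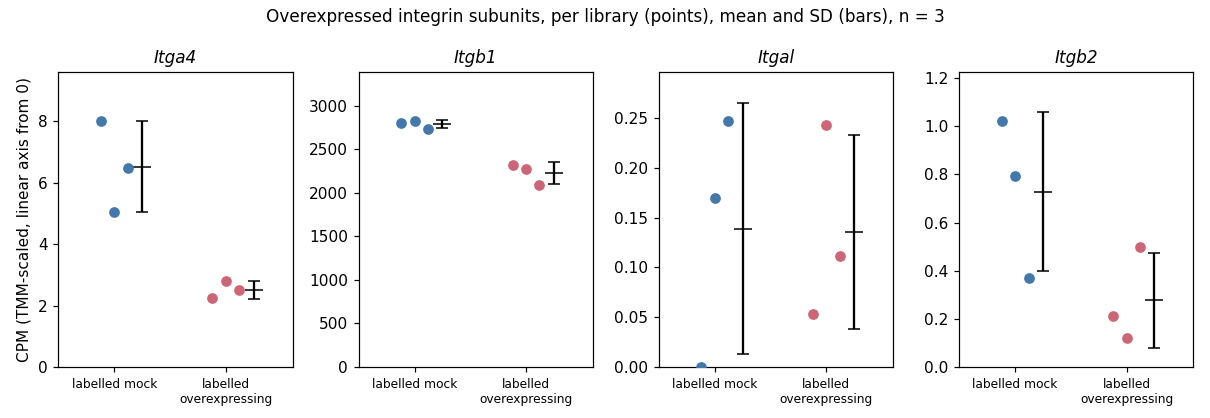
CPM of the 4 overexpressed integrin subunits in each library (points), with the group mean and SD (bars, n = 3), on linear axes from 0, for the libraries labelled mock (blue) and labelled overexpressing (red). Itga4 and Itgb1 were lower in all 3 libraries labelled overexpressing, and no library exceeded 0.247 CPM for Itgal or 1.02 CPM for Itgb2.

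Among the gene lists fixed in advance, interferon-stimulated genes had the median farthest from 0: all 44 tested members were lower in the libraries labelled overexpressing, whose integrin genes go against that label, with a median log2 fold change of -3.71. Most members of the inflammatory, MHC class I, matrix, and hypoxia and glycolysis lists were also lower there. In the antioxidant list 14 of 25 members rose, and its set test was lost with an estimated correlation (adjusted p = 0.0676). Isg15, a ubiquitin-like protein induced by interferon, fell from 189 ± 13.3 to 4.91 ± 0.54 CPM, 38.5-fold. Il6, an inflammatory cytokine, fell from 161 ± 23.4 to 11.6 ± 1.9 CPM, and Col3a1, a fibrillar collagen, from 2658 ± 141 to 605.5 ± 41.0 CPM. Gclm, a subunit of the enzyme that begins glutathione synthesis, rose from 126 ± 5.81 to 346 ± 11.7 CPM.

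By the edgeR test, 6572 of 14502 genes changed (45.3%), 3233 higher and 3339 lower in the libraries labelled overexpressing. Of these, 1207 differed by 2-fold or more, 505 higher and 702 lower. The groups did not overlap for 7744 tested genes (53.4%, where chance gives 10%). Scaling by library size only moved the median log2 fold change of all genes from 0.005 to 0.116 and the share of changed genes that were higher from 49.2% to 65.8% (4598 higher and 2385 lower). The authors' deposited table compared 25991 genes and held 5662 past an adjusted p of 0.05, 2683 higher and 2979 lower. Of the calls in the authors' deposited table, 5571 were also called by edgeR, all with the same sign.

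Most of the largest increases were in genes of low level. Nptx1, a neuronal pentraxin, rose from 0.287 ± 0.244 to 2.46 ± 0.15 CPM, Ano1, a calcium-activated chloride channel, from 0.708 ± 0.268 to 5.33 ± 0.98 CPM, and Bmp2, a bone morphogenetic protein, from 0.265 ± 0.365 to 1.95 ± 0.83 CPM. Without mock replicate 2, Nptx1 was 15.9-fold higher in place of 8.27-fold, and Bmp2, with 2 counts left in the libraries labelled mock, had a ratio of 33 (counting interval 8.91 to 276) in place of a fold of 7.05. Rragd (chromosome 4, 32983037 to 33022180), a Rag GTPase of the lysosomal mTORC1 pathway, rose from 4.57 ± 0.76 to 30.7 ± 1.16 CPM, with a log2 fold change of 2.75 (SE 0.12, adjusted p = 2.37e-14). Aloxe3, Maneal, Med12l, Rdm1, Lce1l, Nudt11, Eef1a2 and Upk1b made up the rest of the 12, with 5.47-fold (Upk1b) to 8.07-fold (Aloxe3) higher levels. The increases with the smallest p were in Cobll1 (2.93-fold), Gclm (2.76-fold), Klf4 (2.49-fold), Adcyap1r1 (2.82-fold) and Srxn1 (2.58-fold).

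The largest decreases held interferon-stimulated genes and markers of Schwann cells, the glia of peripheral nerves. Oas3 (1386 counts over the libraries labelled mock and 23 over those labelled overexpressing) fell 61.5-fold, Cxcl9 (358 and 9 counts) 39.7-fold and Rsad2 (1285 and 34 counts) 38.8-fold. Ifi44 (3681 and 40 counts) fell 94.5-fold and Iigp1 (3377 and 74 counts) 47.1-fold, and without overexpressing replicate 3 these folds were 146 and 71.9. Tgtp2 had 526 and 8 counts, a fold of 65.1 with a counting interval of 34.3 to 159, and without overexpressing replicate 3 its 3 remaining counts gave a ratio of 120 (40.9 to 585). Ifi27l2a had 173 and 4 counts, a fold of 40.8 (17.2 to 166), and all 4 were in overexpressing replicate 2, without which it was at least 41.2-fold lower against a floor of 3 counts over the group. Ifi206, of the interferon-inducible Ifi200 family, had 133 counts over the libraries labelled mock and 0 over those labelled overexpressing, at least 45.9-fold lower against a floor of 3 counts over the group. Cdh19, a cadherin of Schwann cell precursors, had 134 counts and 0, at least 46.2-fold lower against the same floor. Ngfr, the low-affinity neurotrophin receptor, had 852 counts and 8, and fell from 16.6 ± 3.06 to 0.144 ± 0.2 CPM, and without overexpressing replicate 1 its 1 remaining count gave a ratio of 571 (102 to 22600). Sox10, a transcription factor of neural crest and Schwann cells, had 141 counts over the libraries labelled mock and 2 over those labelled overexpressing, a ratio of 73 with a counting interval of 19.8 to 609, and without overexpressing replicate 1, which held both, it was at least 31.5-fold lower against the same floor. The decreases with the smallest p were in Isg15, Ifit1 (22.7-fold), Bst2 (10.6-fold), Itga11 (10.3-fold) and Oasl2 (28.1-fold).

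**Figure D2:**
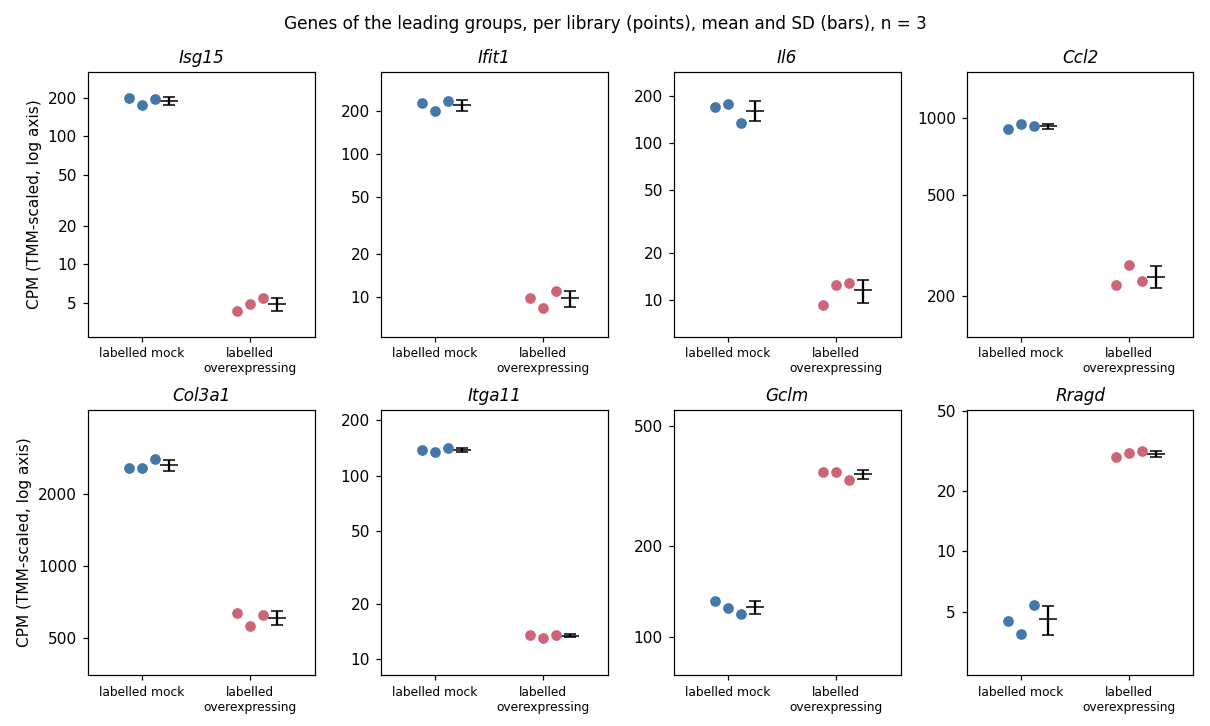
CPM of 8 genes in each library (points), on log axes, with the group mean and SD (bars, n = 3), for the libraries labelled mock (blue) and labelled overexpressing (red). Isg15, Ifit1, Il6, Ccl2, Col3a1 and Itga11 were lower, and Gclm and Rragd higher, in all 3 libraries labelled overexpressing.

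In the immune lists, 0 of 44 interferon-stimulated genes were higher and 44 lower (camera adjusted p = 1.16e-202, and 0.0224 with an estimated correlation). Ifit1, an antiviral RNA-binding protein, fell from 222 ± 19.1 to 9.74 ± 1.32 CPM, and Bst2, which tethers virus particles, from 387 ± 15.5 to 36.5 ± 3.41 CPM. Of 30 inflammatory cytokines and NF-kB targets, 29 were lower and none higher, and 1 was higher without overexpressing replicate 2 or with library size only. Their median was -1.69 (camera adjusted p = 3.43e-33, and 0.0224 with an estimated correlation). The chemokines Ccl2 and Ccl7 fell by 1.96 (SE 0.065) and 1.90 (SE 0.064) on the log2 scale, and Cxcl5, a chemoattractant for neutrophils, by 2.62 (SE 0.065). Of 18 genes of MHC class I presentation, 17 were lower and 1 higher. Their median was -1.16 (camera adjusted p = 1.77e-19, and 0.025 with an estimated correlation). B2m, the light chain of MHC class I, fell from 1254 ± 35.3 to 502 ± 51.4 CPM, and H2-T23, H2-T22 and the loading factor Tapbp fell by 2.15, 1.67 and 1.23 on the log2 scale. Of 27 immunomodulatory and trophic factors, 19 were lower and 4 higher (20 and 4 adjusted over the list alone). Their median was -0.63 (camera adjusted p = 7.67e-07, and 0.025 with an estimated correlation). Igf1, insulin-like growth factor 1, fell from 39.2 ± 0.47 to 9.76 ± 0.62 CPM, and Lgals9, Gas6 and Tgfb2 fell by 1.29, 1.14 and 1.43 on the log2 scale. For the other lists fixed in advance, where no separate count is given, the counts adjusted over the list alone were the same. The Schwann cell markers Cdh19, Ngfr and Sox10 were lower in the same libraries as these groups and as the adhesion, matrix, smooth muscle and glycolysis groups.

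Other integrin subunits were mostly lower: 10 of 17 fell and 2 rose. Their median was -0.42 (camera adjusted p = 6.24e-05, and 0.0311 with an estimated correlation). The count that rose was 1 when any library but overexpressing replicate 3 was left out. Itga11, a collagen receptor subunit, fell from 139 ± 3.59 to 13.5 ± 0.29 CPM, and Itgb5, Itgb3 and Itga8 fell by 0.75, 1.05 and 0.90 on the log2 scale. Of 22 adhesion molecules and integrin ligands, 13 fell and 3 rose (14 and 3 adjusted over the list alone). Their median was -0.47 (camera adjusted p = 2.26e-08, and 0.0311 with an estimated correlation). Postn, a matrix ligand of integrins, fell from 3032 ± 323 to 633 ± 16.5 CPM, Spp1 (osteopontin) from 790 ± 55.2 to 411 ± 7.12 CPM, and the cadherin Cdh11 from 479 ± 2.97 to 240 ± 9.0 CPM, while Mcam fell by 1.82 on the log2 scale. Integrin signalling genes moved both ways, with 11 of 34 lower and 8 higher (12 and 9 adjusted over the list alone). Their median was -0.018 (camera adjusted p = 0.617). Scaled by library size only, 7 were lower and 12 higher, with a median of 0.093, and after the length and GC correction 17 were lower and 6 higher. The scaffold Nedd9 fell by 1.24 and the kindlin Fermt2 by 0.60 on the log2 scale, while Pxn (paxillin) and Git1 rose by 0.71 and 0.58.

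Matrix genes were lower in 33 of 40 and higher in 4, with a median of -0.61 (camera adjusted p = 2.16e-23, and 0.0431 with an estimated correlation). Col18a1 and Col8a1 fell by 2.48 and 1.46 on the log2 scale, and the proteoglycan Ogn from 41.2 ± 0.79 to 7.29 ± 0.15 CPM. Of 28 genes of matrix proteases, inhibitors and migration, 22 fell and 3 rose (22 and 4 adjusted over the list alone). Their median was -0.58 (camera adjusted p = 1.15e-11, and 0.025 with an estimated correlation). Plat and Plau, the plasminogen activators, fell from 75.0 ± 4.43 to 10.96 ± 1.47 CPM and from 172 ± 5.53 to 59.5 ± 5.36 CPM. The protease Adamts2 fell by 1.34 and S1pr1, a sphingosine phosphate receptor, by 2.20 on the log2 scale. Of 19 smooth muscle and myofibroblast genes, 16 fell and 1 rose (17 and 1 adjusted over the list alone). Their median was -0.69 (camera adjusted p = 6.95e-11, and 0.029 with an estimated correlation). None rose without mock replicate 1, mock replicate 3, overexpressing replicate 1 or overexpressing replicate 3. Cnn1 (calponin) fell from 351 ± 2.53 to 130 ± 5.19 CPM, and Actg2, Tpm1 and Myl9 fell by 1.62, 0.83 and 0.69 on the log2 scale. Of 28 hypoxia and glycolysis genes, 22 fell and 3 rose. Their median was -0.55 (camera adjusted p = 1.53e-16, and 0.029 with an estimated correlation). The lactate transporter Slc16a3 fell from 131 ± 15.6 to 16 ± 4.18 CPM. Adm and Pfkl fell by 1.67 and 1.56 on the log2 scale, and P4ha2 fell from 399 ± 20.4 to 162 ± 3.16 CPM.

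Mesenchymal stromal markers fell in 11 of 18 and rose in 4, with a median of -0.45 (camera adjusted p = 0.000409, and adjusted p = 0.0676 with an estimated correlation). Ly6a (Sca-1) fell from 472 ± 1.73 to 155 ± 2.44 CPM, and Thy1 (CD90), Prrx1 and Twist2 fell by 0.89, 0.80 and 1.06 on the log2 scale. Of 14 osteogenic and chondrogenic genes, 7 rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.0432). That call was lost with an estimated correlation (adjusted p = 0.151) and with scaling by library size only (adjusted p = 0.0784). Sox9, a chondrogenic transcription factor, rose from 18.1 ± 1.99 to 58.0 ± 1.83 CPM and Prg4 (lubricin) by 1.07 on the log2 scale, while Col10a1 and the alkaline phosphatase Alpl fell by 0.94 and 3.42. Alpl had only 76 counts over the libraries labelled mock and 7 over those labelled overexpressing, with a counting interval of 5.2 to 28.9 for the ratio. Adipogenic genes went both ways, with 7 of 18 higher and 5 lower (camera adjusted p = 0.268). Cebpa rose from 6.22 ± 0.56 to 19.1 ± 1.15 CPM and Plin4 by 1.44 on the log2 scale, while Fabp5 and Cebpd fell by 1.31 and 1.19.

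Antioxidant genes rose in 14 of 25 and fell in 2, with a median of 0.35 (camera adjusted p = 1.05e-05, and adjusted p = 0.0676 with an estimated correlation). Besides Gclm, the sulfiredoxin Srxn1 rose from 171 ± 5.28 to 441 ± 24.6 CPM and the haem oxygenase Hmox1 from 363 ± 8.79 to 717 ± 62.2 CPM, while the extracellular superoxide dismutase Sod3 fell from 161 ± 19.4 to 62.4 ± 8.65 CPM. Immediate early and dissociation genes rose in 16 of 25 and fell in 6 (16 and 7 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.00109, and adjusted p = 0.229 with an estimated correlation). The transcription factors Klf4 and Klf2 rose by 1.31 and 1.28 on the log2 scale, and the heat shock proteins Hspb1 and Hspa1b by 0.99 and 1.07. In the unfolded protein and integrated stress response list, 14 of 28 rose and 7 fell (camera adjusted p = 0.268), among them the chaperones Pdia4 and Hsp90b1, which rose by 0.65 and 0.63 on the log2 scale, and Slc7a11, which rose by 0.75, while Asns fell by 0.74. P53 targets and senescence genes rose in 13 of 24 and fell in 7 (camera adjusted p = 0.174). Trp53inp1 rose from 164 ± 11.3 to 408 ± 22.4 CPM, Perp and Mdm2 rose by 1.47 and 0.77 on the log2 scale, and Igfbp5 fell by 1.66.

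Cell cycle genes were called in both directions, with 8 of 43 higher and 9 lower (8 and 8 adjusted over the list alone, camera adjusted p = 0.485), and 16 higher and 5 lower when scaled by library size only. Without mock replicate 1 the count higher was 5, and without mock replicate 3 the count lower was 5. Rrm2, Mcm4 and Mcm2, which act in DNA replication, rose by 0.75, 0.57 and 0.37 on the log2 scale, and the thymidylate synthase Tyms fell by 0.78. Cholesterol synthesis genes fell in 7 of 22 and rose in 2 (camera adjusted p = 0.67), and 4 fell and 5 rose when scaled by library size only. The count that rose was 1 without mock replicate 1, mock replicate 2 or overexpressing replicate 3. Insig1 rose by 0.53 on the log2 scale, and Fdft1, Nsdhl and Hmgcs1 fell by 0.56, 0.52 and 0.28. In cholesterol efflux and lipid uptake, 6 of 16 rose and 6 fell (6 and 7 adjusted over the list alone, camera adjusted p = 0.817). The lipoprotein receptor Lrp1 rose from 2870 ± 171 to 4598 ± 186 CPM and the efflux transporter Abca1 from 98.8 ± 8.4 to 147 ± 8.58 CPM, while the oxidised LDL receptor Olr1 and the cholesterol carrier Npc2 fell by 1.37 and 0.45 on the log2 scale.

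Ribosomal protein genes fell in 68 of 72 and rose in none (69 lower adjusted over the list alone), with a median of -0.48 (camera adjusted p = 4.52e-16, and adjusted p = 0.251 with an estimated correlation). Rps4x fell from 674 ± 8.87 to 430 ± 29.7 CPM, and Rpl21, Rpl7 and Rps6 fell by 1.27, 0.60 and 0.56 on the log2 scale. Short genes as a whole were lower in the same libraries: over protein-coding genes the median log2 fold change was -0.16 in the shortest of 10 equal bins by length and 0.14 in the longest, with a Spearman correlation of 0.2 across genes, which are not independent replicates. Of the 12 tested mitochondrially encoded genes, 4 fell and none rose (camera adjusted p = 0.425). Without overexpressing replicate 1, 2 fell, without overexpressing replicate 3, 5 fell and 1 rose, and after the length and GC correction 1 fell. Mt-Cytb fell by 0.30 on the log2 scale, and mt-Nd1, mt-Co1 and mt-Nd2 by 0.30, 0.24 and 0.17. The calls of mt-Nd1, mt-Co1 and mt-Nd2 were lost after the length and GC correction, and the list median of -0.10 was 0.007 when scaled by library size only.

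Markers of other cell types passed the filter only in part. Of 27 monocyte and macrophage markers 5 could be tested, of which 2 fell and none rose (camera adjusted p = 0.396): Mpeg1 fell from 3.02 ± 0.27 to 0.281 ± 0.191 CPM (10.5-fold, and 17.1-fold without overexpressing replicate 3) and Csf1r from 13.1 ± 1.81 to 8.42 ± 1.23 CPM. Lyz2 had 3.90 ± 1.04 and 2.66 ± 0.72 CPM (adjusted p = 0.0743), and 0.0338 and 0.0247 without mock replicate 1 and without overexpressing replicate 2, and Cd68 had 3.14 ± 0.33 and 3.95 ± 1.04 CPM (adjusted p = 0.255). Of 11 tested endothelial markers 6 fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.132). Ecscr, Flt1 and Pecam1 fell, with log2 fold changes of -2.65, -1.64 and -2.74, and Tek rose, with 1.36. Pecam1 had only 67 counts over the libraries labelled mock and 10 over those labelled overexpressing, with a counting interval of 3.55 to 15.1 for the ratio. Of 5 tested mesothelial and epithelial markers 3 fell and 1 rose (3 and 2 adjusted over the list alone, camera adjusted p = 0.501). The keratins Krt7 and Krt19 fell by 2.97 and 0.43 on the log2 scale, and Krt7 fell 12.3-fold without overexpressing replicate 2 in place of 7.85-fold. Nkain4 rose by 1.02 and Bnc1 fell by 0.95, and both calls were lost under several settings. In this list 2 rose without mock replicate 1, and none without mock replicate 2 or overexpressing replicate 1. Of the lymphocyte markers 1 could be tested, Trac, at 4.25 ± 0.82 and 3.51 ± 0.33 CPM (adjusted p = 0.307).

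**Figure D3:**
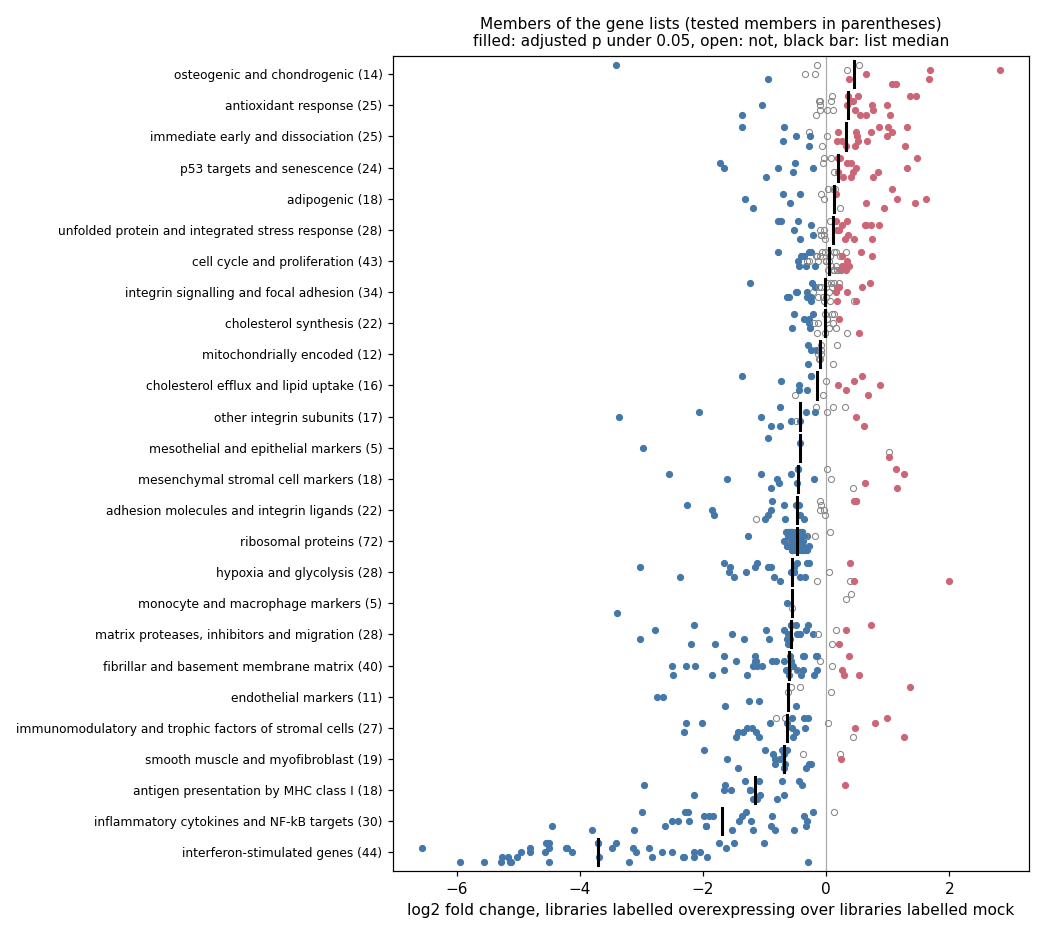
Log2 fold change (x axis, libraries labelled overexpressing over libraries labelled mock) of each tested member of the 26 lists with at least 5 tested members, sorted by list median (black bars), with the number of tested members in parentheses. Filled points passed an adjusted p of 0.05 (red higher, blue lower) and open points did not, and all 44 interferon-stimulated genes lie below 0, with a median of -3.71.

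Over the 26 lists with a set test, camera called 15, of which 3 were higher and 12 lower. With an estimated correlation 10 of the 15 held, at camera adjusted p of 0.0224 to 0.0431. Fry, which tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes, called 20 lists. With 3 libraries against 3, an exact permutation test of a single gene cannot go below p = 0.1, so the calls rest on the spread that edgeR shares across genes.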

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

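The length and GC correction was the only alternative chosen after seeing the data. Across the planned scalings, tests and filters, the count of changed genes lay between 5693 (DESeq2) and 6983 (library size only), against 6572. Of the 6572 calls, 5615 were shared with DESeq2, 6481 with limma-voom and 5618 with library size only. An adjusted p of 0.01 left 4956 genes, protein-coding genes alone gave 6193, and the length and GC correction gave 6562, of which 5715 were shared. A 2-fold minimum left 1207 changed genes, 505 higher and 702 lower, because it sets a stricter criterion on the same fit. Leaving out 1 library at a time gave 5732 to 6361 changed genes, 2785 to 3118 higher and 2912 to 3243 lower, with 1 sample fewer in each fit. Equal replicate numbers did not pair the libraries: the deviations from the group means correlated at 0.01, 0.016 and 0.003 for numbers 1, 2 and 3. The fit with the replicate block called 6480 genes, 3183 higher and 3297 lower, and gave log2 fold changes of -1.37 for Itga4 and -0.32 for Itgb1.

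The thresholds and the protein-coding subset were applied to the counts of genes only. In the other refits Itga4 kept its direction and its call, from -1.54 (without mock replicate 2) to -1.2 (without mock replicate 1), as did Itgb1, from -0.35 (without overexpressing replicate 1) to -0.21 (library size only). Of 130 named genes with a test, 124 kept their direction and side of the threshold in every one of these refits and none reversed. The other 6 were Lyz2, Nkain4, Bnc1, mt-Nd1, mt-Co1 and mt-Nd2. The cause was not tested. With an estimated correlation 5 list calls were lost, and with library size only 1. The length and GC correction added calls of the p53 and unfolded protein lists (adjusted p = 0.0481 for both), and random lists added the endothelial and p53 lists (adjusted p = 0.00409 and 0.0153). With all 6 libraries Itgal and Itgb2 did not pass the filter, while Itgb2 passed it in 4 of the fits that left out 1 library and was lower in 2 of them (adjusted p = 0.0361 and 0.0265). A gene with no counts in a library lay below 0.163 to 0.191 CPM there.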

Other observations

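The tests of exchanged labels, of uncounted transgene sequence, of leukocytes and of a mixed mock library were chosen only after the results they bear on were seen. The Schwann cell and melanocyte tests were written before their markers were examined, but after the values of Sox10, Ngfr and Cdh19 had been seen, which the marker lists leave out. The 5 added lists and the gene families below were also chosen after seeing the data.

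Of 6 gene families counted beyond the lists, 3 fell in every tested member, and the interferon-stimulated gene list holds some of those members. All 14 tested guanylate-binding proteins and immunity-related GTPases, all 8 of the Ifi200 family and all 4 Schlafen genes fell in the libraries labelled overexpressing, with median log2 fold changes of -3.72, -3.14 and -2.70, and the same counts fell when scaled by library size only. Slfn2, of the Schlafen family, fell from 90.9 ± 6.25 to 4.06 ± 0.68 CPM. The 20 interferon genes had 2, 5 and 1 counts in the libraries labelled mock and 0 in each labelled overexpressing. Of 37 proteasome subunits 6 rose and 9 fell, while 16 rose and 4 fell when scaled by library size only. This family includes Psmb8, Psmb9 and Psmb10, which are also in the MHC class I list, where 17 of 18 fell.

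Among heat shock proteins and co-chaperones, 18 of 21 rose and 1 fell, with a median of 0.43 (camera adjusted p = 1.24e-08, and adjusted p = 0.0748 with an estimated correlation). The heat shock proteins Hspb1 and Hspa1b, given above, rose in a list fixed in advance. The set test of the heat shock list may therefore partly reflect genes already seen. Hsp90aa1, a cytosolic chaperone, rose from 860 ± 55.6 to 1105 ± 34.6 CPM. Lysosome and autophagy genes rose in 14 of 29 and fell in 9 (camera adjusted p = 0.00933, and adjusted p = 0.195 with an estimated correlation), and the autophagy receptor Sqstm1 rose from 794 ± 46.2 to 1461 ± 21.3 CPM. The largest log2 fold change in this list was 2.75, the value given above for Rragd, so its set test may partly reflect a gene already seen. The metallothioneins Mt1 and Mt2, which bind zinc and copper, rose from 118 ± 28.2 to 314 ± 16.2 CPM and from 8.65 ± 1.55 to 28.6 ± 3.32 CPM. Of 37 histone genes 10 rose and 5 fell. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y had 0 counts in all 6 libraries, and Xist had 8968 to 9999.

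The overexpressed subunits were not higher in the libraries labelled overexpressing. An exchange of the group labels would place Itgal and Itgb2 in the libraries labelled mock. Their highest level in any of the 6 libraries was 1.02 CPM, which argues against an exchange alone as the cause of their missing reads. It cannot tell whether the labels were exchanged, because uncounted transgene sequence would give these levels with either labelling. For Itga4 and Itgb1 an exchange cannot be told apart from a true decrease, since the log2 fold change of -1.38 for Itga4 has the sign that an exchange would give. The Itgb2 counts of 38 and 15 (ratio 0.381, counting interval 0.195 to 0.709) go the same way, but Itgb2 did not pass the filter with all 6 libraries. Transgene sequence that the mouse gene counts do not take may also be present: the 7 Itgal counts over the libraries labelled overexpressing would look the same with or without it, and the vector sequence was not used here. A lack of expression of the transgenes stays open as well.

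Interferon-stimulated genes were lower in the libraries labelled overexpressing. Monocytes or macrophages in the cultures labelled mock would bring their own abundant transcripts, but the median of their markers there lay below the 3-count floor. Its ratio to the 66.6 CPM of the median interferon-stimulated gene was 0.00114, and 0.00266 with the markers set at the floor. Ptprc had 8 counts over the libraries labelled mock and 5 over those labelled overexpressing. These values argue against these cells as the source of the interferon-stimulated transcripts, and the test was not run for other leukocytes. A small share of such cells stays open, since 2 of the 5 tested markers fell with the interferon-stimulated genes: Mpeg1 from 3.02 ± 0.27 to 0.281 ± 0.191 CPM (10.5-fold, adjusted p = 4.64e-07, and 17.1-fold without overexpressing replicate 3) and Csf1r from 13.1 ± 1.81 to 8.42 ± 1.23 CPM (adjusted p = 0.000797). The other 3 were not called, among them Lyz2 (edgeR adjusted p = 0.0743) and Cd68 (0.255), whose mean was higher in the libraries labelled overexpressing. All 44 members stayed lower after the length and GC correction and all 44 with library size only, which argues against these as the whole cause. The pattern may be biological, as a hypothesis: an interferon response in the cultures labelled mock, or its loss in the others, is a candidate explanation that was not tested, and which cultures carried the empty vector depends on labels that the integrin genes go against.

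Schwann cell transcripts Sox10, Ngfr and Cdh19 were near 0 in the libraries labelled overexpressing. A single mixed library labelled mock is argued against as the source of the Ngfr transcripts only. Among the 3, the highest Ngfr level was 1.45 times the lowest. Melanocytes as the source of these transcripts are argued against by their markers, of which 2 of 10 reached 20 counts. Tyr, Dct and Tyrp1 had 0, 0 and 1 counts over the libraries labelled mock. A small share of melanocytes stays open, since Pmel had 47 and 25 counts over the groups and Mlana 14 and 3. Tyrp1, Dct, Slc45a2, Oca2 and Trpm1 had more counts in the libraries labelled overexpressing. Schwann-like cells in the cultures labelled mock stay open. Of the 32 other Schwann cell markers 21 were tested, of which 11 fell and 1 rose (12 and 2 adjusted over the list alone). Camera gave an adjusted p of 0.0176, and 0.142 with an estimated correlation. The median of the tested markers, -0.67, lay at percentile 0 of random lists matched on expression, which take the genes as independent. For the 25 with at least 20 counts, the median log2 ratio was -0.78, short of the -1 set in advance for such cells. The other part of that criterion, on the share of tested markers called lower, was met. Named after their values were seen, Foxd3 had 57 and 0 counts over the groups and Erbb3 60 and 17. In mock replicates 1, 2 and 3, Foxd3 had 36, 9 and 12 counts and Erbb3 33, 13 and 14. Both were highest in mock replicate 1, which the Ngfr ratio does not cover, while Cdh19 (41, 55 and 38) and Sox10 (46, 34 and 61) were not. Mbp had 155 and 101 counts over the groups and was called lower (edgeR adjusted p = 0.0433), while S100b had 193 and 203. A loss of these transcripts from the ADSC themselves was not tested.

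The ribosomal protein genes kept a median of -0.41 and 68 lower members after the length and GC correction, and their uncorrected median lay at percentile 0 of 10000 lists matched on length and expression, whose central range was -0.295 to -0.12. Random lists take the genes as independent, while the ribosomal list had an estimated correlation of 0.563, with which its camera call was lost (adjusted p = 0.251). TOP mRNAs outside the ribosomal proteins had 14 of 21 lower and 1 higher, and their median of -0.31 lay at percentile 4.02 of lists matched on length and expression and at percentile 0.57 of lists matched on expression alone (camera adjusted p = 0.00426, and adjusted p = 0.142 with an estimated correlation), against the lowest 2.5% that had been set in advance. The melanocyte list had 1 tested gene, Pmel, which was not called.

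The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 6572 changed genes, and 1 of the 10 splits, the real one, gave as many. The highest of the other splits gave 0 genes by the edgeR test, and 120 to 218 genes at an unadjusted p under 0.05, where the real split gave 7535. Each of the other splits puts libraries of both groups on each side, so the group difference adds to the spread within a side. Their low counts follow from this and are no reference for chance. Other tools were not run on the splits.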
